A study of Mus musculus with 4 samples.

How the data were processed

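RNA was measured on 4 Affymetrix Mouse430_2 arrays, which carry short oligonucleotide probes grouped into probe sets, each aimed at 1 transcript. The cells were macrophages grown from the bone marrow of MyD88-deficient mice for 6 days in recombinant human M-CSF, the growth factor that drives marrow precursors toward macrophages. Per the labels, 2 arrays came from unstimulated cells (0 min) and 2 from cells given zymosan, a yeast cell wall preparation, at 100 ug/ml for 120 min, and biotin-labelled cRNA was made from 4 ug of total RNA. The labels do not say whether the arrays of a group came from separate mice or cultures, so the p-values measure the spread between these arrays, which may be technical in part.

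The deposited values are log2 expression values, 1 per probe set and array, made by the authors with RMA, per the submitters' processing notes. RMA subtracts background, equalizes the distributions of the arrays and summarizes the probes of each probe set. Its version and the set of arrays normalized together are not given in the sources used here. The array medians lay between 4.92 and 4.95 and the values between 2.35 and 14.5, so no further normalization was applied in the main analysis. The scanner's settings files hold no expression values. They were used for the chip type and for which arrays shared a processing day, operator number and project. All 4 columns of values were used, and no other column of array values was present.

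Probe sets were named from the platform annotation. Of the 45037 probe sets left after 64 controls were set aside, 34945 had 1 gene symbol, 932 had several and 9160 had none there. No gene was named from a probe set with several symbols. A probe set was kept when it reached the 40th percentile of the array in at least 2 arrays, which left 27571. Each gene was represented by its probe set of highest mean, which left 13220 genes. No coordinates are given, since no genome build was named for the array.

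Differences are zymosan minus unstimulated on the log2 scale. They were tested with lmFit and eBayes in limma 3.58.1 under R 4.3.3, with a 2-sided test, Benjamini-Hochberg adjustment over all kept probe sets or genes, and a threshold of adjusted p under 0.05. All adjusted p-values of genes and probe sets come from that fit. The standard error (SE) is limma's moderated one, and the SD is over the 2 arrays of a group. With 2 arrays against 2, an exact permutation test cannot give a 2-sided p under 0.333, so limma's test rests on sharing the variance across genes. The number of arrays limits the precision of each value. RMA gives a value even where a transcript is absent. Where every array of a group lay below the filter's level (4.36 to 4.39), the fold was therefore computed against that level and is given as at least that large, a choice made after the data were examined. Of the genes called 2-fold higher, 23 had every unstimulated array below the level, and 13 of them were at least 2-fold higher against it. Of those called 2-fold lower, 7 had every zymosan array below the level, and 4 were at least 2-fold lower against it. Counts of genes by fold and medians of lists use the fitted values.

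Before the data were examined, 32 gene lists were fixed. They covered cytokines, chemokines, immediate early transcription factors, NF-kB feedback and targets, type I interferon response, MAP kinase and receptor feedback, NFAT and calcineurin targets, eicosanoids, recognition receptors and adaptors, and phagocyte oxidase. Further lists covered NRF2 targets, cholesterol synthesis, LXR targets, glycolysis and hypoxia, ER stress, heat shock, cell cycle, macrophage identity, chemotactic and purinergic receptors, antigen presentation, alternative activation, lysosome and autophagy, apoptosis and housekeeping genes. The last 8 held markers of T and NK cells, B cells, neutrophils, dendritic cells, mast cells and basophils, erythroid cells and megakaryocytes, stromal fibroblasts, and sex-linked genes. The 30 lists with at least 5 kept genes were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. They were tested again with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way.

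The rule for named genes was also fixed before the data were examined. It took the 12 largest increases and the 12 largest decreases among genes past the threshold whose arrays did not overlap between groups, up to 4 genes of smallest p in each list, and 20 genes of interest. These were Myd88, Ticam1, Clec7a, Tlr2, Card9, Syk, Tnf, Il1b, Il6, Il10, Il12b, Ifnb1, Ptgs2, Egr2, Egr3, Nfkbiz, Cxcl2, Nos2, Actb and Gapdh. Of the genes it named, 141 were tested. All were recomputed under each alternative, except that 125 passed the filter at the 60th percentile and 134 that on the mean of all probe sets. Other list members, other probe sets of a gene, gene families and a second granulocyte panel are also named, and these were chosen after the main values were seen, although the values of the panel had not been.

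The alternatives were no filter, a filter at the 60th percentile, centring on the median, a second quantile normalization, eBayes with trend and robust settings, array weights, the mean of all probe sets of a gene, adjusted p under 0.01, a minimum fold of 1.5 with treat, and leaving out each array in turn. The alternative chosen after seeing the data took the processing day as a random block. Its correlation within a day was 0.540 for probe sets and 0.567 for genes, estimated by pooling the variance between the same-day zymosan arrays against that between the unstimulated arrays of different days, since limma's own estimator gave none with 4 arrays. Random lists numbered 10000 and were matched on mean expression in 20 bins, and permutation tests used 100000 resamples.

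The test was run on simulated data with the means and spreads of the 27571 kept probe sets, 200 of them changed, in 10 simulations. It recovered 0% of changes of 1.5-fold, 26.6% of 2-fold, 68.4% of 4-fold and 84.6% of 8-fold, and 1.10% of its calls were false. Spreads were shuffled across probe sets, both groups shared the same spread and no day effect was added. On the real arrays 4393 probe sets were called, so these percentages do not carry over to them. In 10 simulations over 13220 genes, the set test called the list shifted by 0.5 in 10 and called 0 of 290 unshifted lists. Genes were drawn independently there, so this cannot show how often an unshifted list is called when its genes move together. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.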

Results

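Gene expression was measured in bone marrow-derived macrophages that lack MyD88, the adaptor through which most Toll-like receptors and the interleukin-1 receptor signal. Cells left unstimulated (2 arrays) were compared with cells given 100 ug/ml zymosan for 120 min (2 arrays). Zymosan is a particle of yeast cell wall that is rich in beta-glucan and is recognized by Toll-like receptor 2 and by the lectin Dectin-1, the product of Clec7a. The comparison asks which transcripts differed after 2 h of zymosan when MyD88 was absent. No wild-type array was analysed here, so it cannot be said which differences depend on MyD88.

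The arrays of a group were closer to each other than to those of the other group. Over the 27571 kept probe sets, the unstimulated arrays correlated at r = 0.989 across probe sets, with an SD of their differences of 0.29 and 214 probe sets at least 2-fold apart. The zymosan arrays correlated at r = 0.995, with an SD of 0.20 and 9 probe sets 2-fold apart. Between groups r was 0.964 to 0.969, and 1424 to 1767 probe sets lay 2-fold apart. Probe sets are not independent replicates. The unstimulated arrays were processed 16 days apart, and both zymosan arrays on 1 further day, 153 days after the first, by another operator and under another project. The titles of the unstimulated arrays carry the letters LPS and PIC, and those of the zymosan arrays ZYM. No day held arrays of both groups, so day, operator and stimulus cannot be told apart in any result below.

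Myd88 itself had a log2 value of 8.75 ± 0.04 (SD, n = 2) in unstimulated and 8.38 ± 0.02 (SD, n = 2) in zymosan arrays. The difference of -0.37 (SE 0.10) did not pass the test (adjusted p = 0.0506). The position of its probes relative to the deleted part of the gene is not known here, and all 4 arrays are labelled deficient, so these values check no label. Ticam1, the adaptor of the MyD88-independent pathway of Toll-like receptors, differed by 0.09 (SE 0.12, adjusted p = 0.641).

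Zymosan-treated macrophages had a broad change in transcripts. Ranked by the probe set of highest mean for each gene, it was led upward by a lysosomal channel, a macrophage growth factor and an early growth response factor, and downward by interferon-induced genes. A probe set of Egr3, another early growth response factor, that did not represent its gene had a larger fitted difference than these and rose at least 30.6-fold. Mcoln3, an endolysosomal cation channel, rose at least 19.8-fold, to 8.70 ± 0.07 from 4.05 ± 0.13 (log2, SD, n = 2 per group), which was below the filter's level. Csf1, which encodes M-CSF, rose 21.1-fold at the probe set that represented it, from 6.29 ± 0.01 to 10.68 ± 0.01. Its other probe sets rose by 3.32 and 0.75 on the log2 scale or differed by 0.25 without passing the test (adjusted p = 0.203). Egr2, an early growth response transcription factor, rose 11.5-fold, and Ptgs2, the inducible cyclooxygenase, rose at least 6.18-fold from below the filter's level. Ifi27l2a, an interferon-induced gene, was 10.7-fold lower after zymosan, at 9.36 ± 0.08 against 12.77 ± 0.20. The next largest decrease was that of Ifit1, also interferon-induced, which was 10.3-fold lower.

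The other large increases in that ranking, all past the threshold with no overlap between the arrays of the groups, were those of Mmp8, Cxcl3, Egr1, Hspa1b, Mpo, Cd69, Chil3 and Hspa1a, with log2 differences from 3.13 to 3.48. Cxcl3 and Cd69 rose from below the filter's level, by at least 4.04-fold and 5.66-fold. Mmp8 and Mpo encode a neutrophil collagenase and myeloperoxidase, Cd69 an early activation antigen of leukocytes, and Hspa1a and Hspa1b inducible heat shock proteins. The remaining large decreases were those of Rtp4 (-3.11), Oasl2 (-3.10), Ifit3 (-3.01), Ctse (-2.95), Irf7 (-2.81), Cx3cr1 (-2.77), Uchl1 (-2.73), Mx1 (-2.59), Dusp6 (-2.49) and Pltp (-2.45). Rtp4, Oasl2, Ifit3, Irf7 and Mx1 are interferon-induced, Cx3cr1 is the fractalkine receptor, and Pltp encodes the phospholipid transfer protein. Another probe set of Ctse differed by -0.04 (adjusted p = 0.853) and another of Rtp4 by -1.18 (adjusted p = 0.0534), neither past the threshold. For Mmp8, Ifit1, Ifit3, Ctse, Irf7, Cx3cr1, Uchl1 and Dusp6 the unstimulated arrays lay apart from each other, with SDs from 0.67 to 1.25.

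In all, 2339 probe sets were higher and 2054 lower with zymosan by limma's test. At the level of genes, 1335 were higher and 890 lower. Of these, 277 were higher and 209 lower by at least 2-fold, 51 and 32 by at least 4-fold, and 14 and 5 by at least 8-fold. The counts of probe sets depended on the close agreement of the same-day zymosan arrays. They were 354 and 412 without zymosan replicate 1, 231 and 157 without zymosan replicate 2, and 741 and 647 with the processing day as a random block, an alternative chosen after seeing the data. The counts of genes at least 2-fold higher and lower were 189 and 127 without zymosan replicate 1, 161 and 100 without zymosan replicate 2, and 135 and 76 when limma's treat tested for a minimum fold of 1.5.

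**Figure D1:**
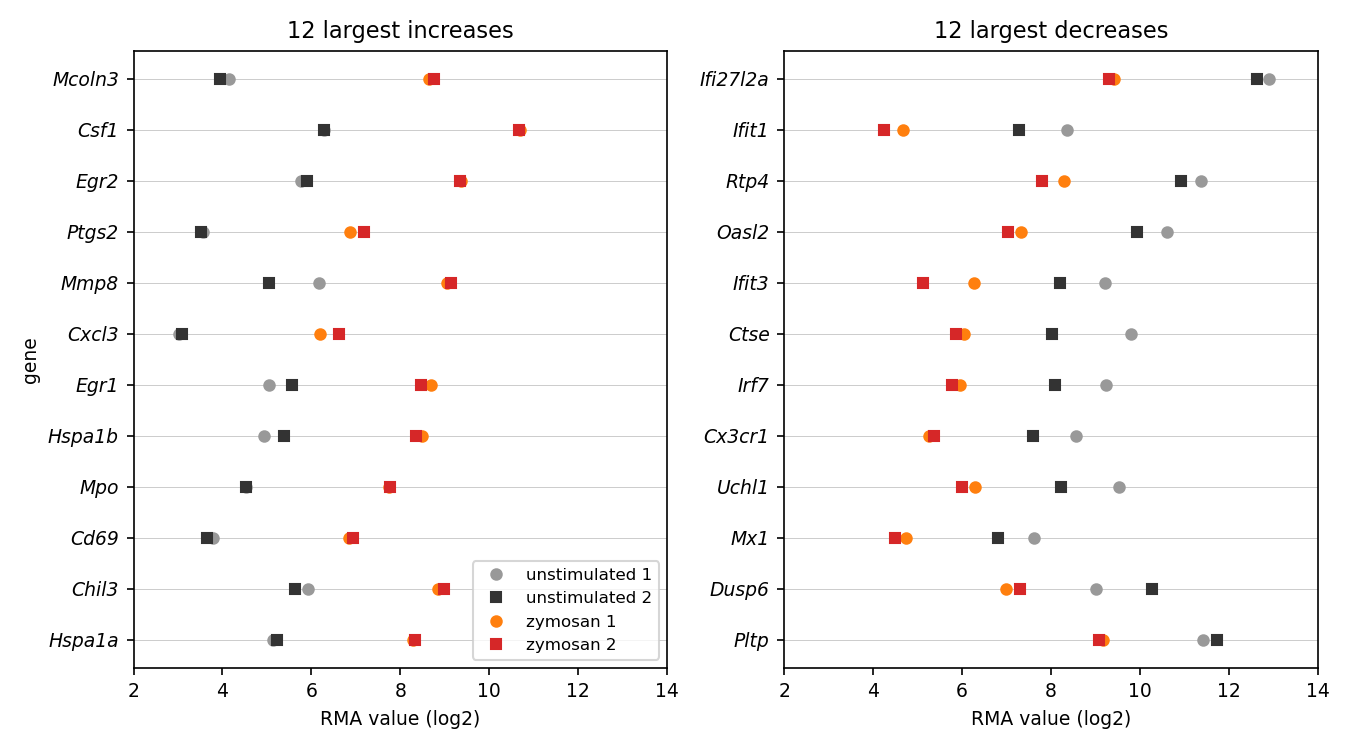
RMA values (log2, x axis) of the 12 genes with the largest increases (left) and the 12 with the largest decreases (right), at the probe set that represented each gene, on each of the 4 arrays, 1 symbol per array. The arrays of the groups do not overlap for any of the 24 genes, and Ctse has the widest spread within the unstimulated pair (SD 1.25).

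The NF-kB feedback and target genes rose as a group. Of 32 measured, 23 rose and 9 did not pass the test, and 26 were higher when adjusted over the list alone. Tnfaip3, the deubiquitinase A20 that restrains NF-kB signalling, rose 6.21-fold, from 7.80 ± 0.01 to 10.43 ± 0.03 (SD, n = 2). The inhibitor gene Nfkbie rose 3.62-fold, Bcl3, an atypical NF-kB inhibitor family member, 3.40-fold, and the adhesion molecule gene Icam1 rose by 1.32 on the log2 scale. Nfkbiz, which encodes the nuclear inhibitor IkB-zeta, rose 5.40-fold. The list median was 1.08 and camera called the list (adjusted p = 3.64e-14). The call was lost with an estimated correlation (adjusted p = 0.326 with an estimated correlation). That correlation was -0.02, below the preset 0.01, so genes moving together do not account for the loss. Without zymosan replicate 1 or zymosan replicate 2, 12 and 13 members were higher.

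Cytokine genes went both ways, with more higher than lower. Of 15 measured, 9 rose and 2 fell, or 10 and 2 adjusted over the list alone. Besides Csf1, Tnf rose 3.60-fold, Il1b 3.58-fold and Il1rn, the interleukin-1 receptor antagonist, 5.44-fold. Il10, an anti-inflammatory cytokine, fell at least 2.22-fold (adjusted p = 0.0053), to below the filter's level, and Ebi3 fell by 0.64. Il6 and Il12b were below the filter. The list was called by camera (adjusted p = 0.00083) and not with an estimated correlation (adjusted p = 0.440 with an estimated correlation). Of the cytokine genes, 7 and 6 were higher without zymosan replicate 1 or zymosan replicate 2, and limma called 0 and 1 lower, where 2 had an unadjusted p under 0.05 each time.

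Of 24 chemokine genes, 9 rose and 2 fell, or 10 and 3 adjusted over the list alone. Cxcl3 rose at least 4.04-fold and Cxcl2 4.99-fold, both ligands of the neutrophil receptor Cxcr2, and Ccl6 rose 2.39-fold. Cxcl16, a ligand and scavenger receptor, was 2.33-fold lower, and Ccl5 fell by 0.76. The list had a median of 0.23 and was called by camera (adjusted p = 0.00718), though not in the second form of the test (adjusted p = 0.476 with an estimated correlation). Without zymosan replicate 1 or zymosan replicate 2, 3 members were higher each time, and limma called 0 lower, where 2 and 3 had an unadjusted p under 0.05. Cxcl1 differed by 0.24 at the probe set that represented it (adjusted p = 0.189), while others of its probe sets rose 10.5-fold (adjusted p = 0.00097) and by 1.94 on the log2 scale (adjusted p = 0.00354).

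Immediate early transcription factors rose in part. Of 30 measured, 10 rose, or 12 adjusted over the list alone, led by Egr2 and Egr1 (9.63-fold). Junb, a subunit of AP-1, rose 2.98-fold and the orphan nuclear receptor Nr4a1 2.58-fold. Fos (-0.40), Jun (0.10) and Myc (0.28) did not pass the test. Egr3 gave unlike readings at its probe sets. The one of higher mean over the 4 arrays, which represented the gene, differed by -0.14 (SE 0.10, adjusted p = 0.393). It was at 6.36 on the zymosan arrays. The other rose at least 30.6-fold, to 9.32 ± 0.36 (SD, n = 2, adjusted p = 0.0011), from below the filter's level. The list was called by camera (adjusted p = 0.000557), not with the correlation taken from the data (adjusted p = 0.554 with an estimated correlation), and 6 members were higher when 1 or the other zymosan array was left out. The list also differed within the unstimulated pair, by a median of -0.16 (unstimulated 1 minus unstimulated 2), outside the central 95% of random lists (-0.05 to 0.13). Its median with zymosan was 0.27, and 0.16 without unstimulated replicate 1, where 2 members were lower.

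Type I interferon response genes were lower after zymosan. Of 37 measured, 30 fell and 1, Irf1, rose, or 32 and 1 adjusted over the list alone. Besides those named above, Xaf1 was 4.14-fold lower (9.40 ± 0.33 against 7.35 ± 0.09, SD, n = 2), Irf9, a subunit of the interferon-activated factor ISGF3, was 2.63-fold lower, and Usp18 fell by 2.04. Irf1, which NF-kB also induces, rose 4.17-fold. Ifnb1, the gene of interferon-beta, was below the filter. The list median was -1.38 and camera called the list (adjusted p = 4.85e-18). Its members moved together (estimated correlation of 0.75), and the call was lost in the second form of the test (adjusted p = 0.554 with an estimated correlation). That form called no list, also none with a negative correlation, so the loss cannot be laid to the value of 0.75 alone. The same genes differed within the unstimulated pair, where 36 of 37 were higher on unstimulated 1 and the median difference was 0.50. Without zymosan replicate 1 or zymosan replicate 2, 13 and 9 members were lower.

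**Figure D2:**
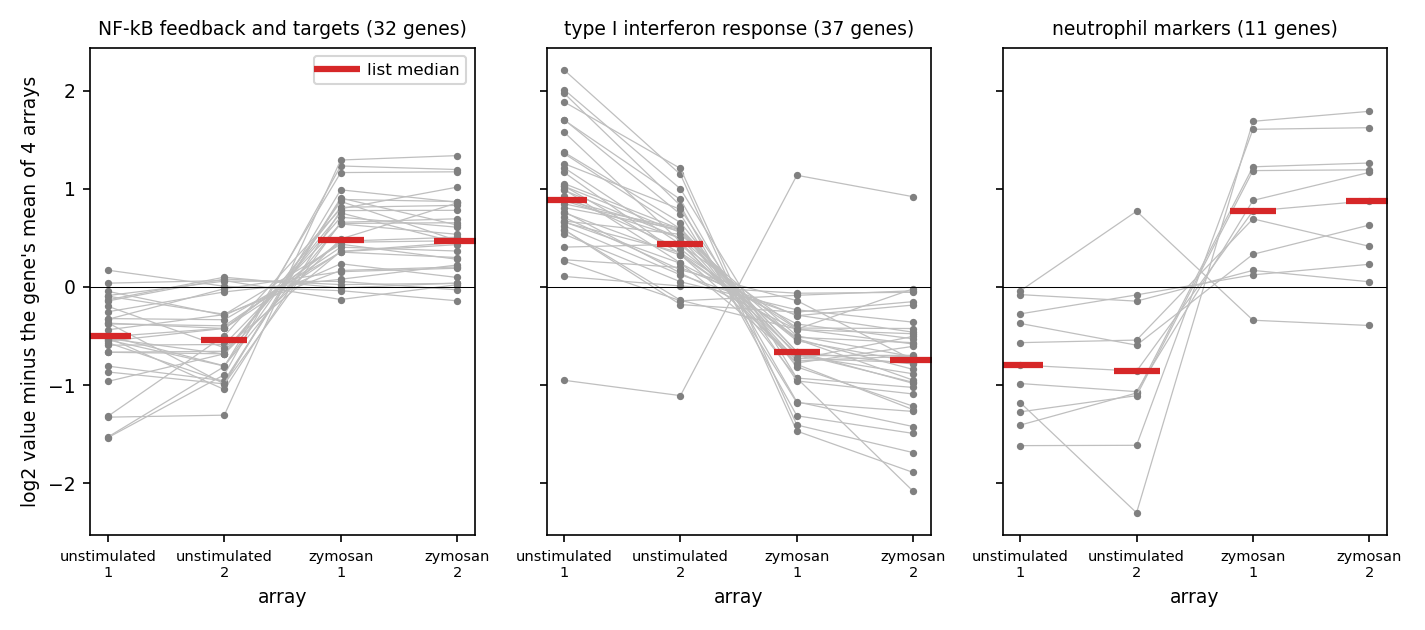
Each gene's log2 value minus its mean over the 4 arrays (y axis) on each array (x axis), for the NF-kB, interferon and neutrophil marker lists. Grey lines join the values of 1 gene and red bars are list medians, which for the interferon list were 0.89 and 0.44 on the unstimulated and -0.66 and -0.74 on the zymosan arrays.

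Heat shock genes rose. Of 12 measured, 7 rose, or 9 adjusted over the list alone. Hspa1b rose 9.59-fold and Hspa1a 8.78-fold, the mitochondrial chaperone Hspd1 1.78-fold and Hsph1 1.69-fold. The camera adjusted p was 1.72e-06 (adjusted p = 0.326 with an estimated correlation), and 2 members were higher when 1 or the other zymosan array was left out. NRF2 antioxidant genes rose in part, with 8 of 17 higher and 2 lower, or 9 and 2 adjusted over the list alone. The metallothioneins Mt2 and Mt1 rose 4.51-fold and 2.47-fold and sulfiredoxin, Srxn1, 2.38-fold at 1 of its 4 probe sets, while Osgin1 was 1.97-fold lower. Camera called this list (adjusted p = 0.00543; adjusted p = 0.712 with an estimated correlation), 4 members were higher with the day as a random block and 2 when 1 or the other zymosan array was left out. In the latter case limma called 0 lower, where 2 had an unadjusted p under 0.05 each time.

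Part of the genes of sterol synthesis and of glycolysis and the hypoxia response were higher. Of 20 cholesterol synthesis genes 11 rose, or 16 adjusted over the list alone, among them Hmgcs1 (2.62-fold), Sc5d (1.97-fold), Sqle (1.88-fold) and Nsdhl (1.55-fold). The list median was 0.52 (camera adjusted p = 1.5e-06, adjusted p = 0.554 with an estimated correlation). Of 20 glycolysis and hypoxia genes 9 rose, or 14 adjusted over the list alone, among them the oxygen sensors Egln3 (3.79-fold) and Egln1 (1.52-fold), Pfkl (2.20-fold) and P4ha1 (2.04-fold). Its median was 0.53 (camera adjusted p = 1.72e-06, adjusted p = 0.586 with an estimated correlation). The NRF2 median was 0.56, and 0.32 without unstimulated replicate 2 (camera adjusted p = 0.0421), and 1 NRF2 gene was lower without unstimulated replicate 1. The NRF2, sterol and glycolysis lists also differed within the unstimulated pair, with medians of 0.34, 0.19 and 0.36 higher on unstimulated 1. With the day as a random block, 5 sterol and 3 glycolysis genes were higher, and without unstimulated replicate 1 there were 16 of each. When 1 or the other zymosan array was left out, limma called 2 glycolysis and 0 sterol genes, although 13 and 14 sterol genes had an unadjusted p under 0.05.

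Cell cycle genes moved little. Of 31 measured, 5 rose and 1 fell, the same numbers adjusted over the list alone. Mki67, a marker of cycling cells, rose 1.61-fold, Ccne2 1.47-fold, Mcm2 1.39-fold and Cdk1 1.39-fold, and Rrm1 fell by 0.54. The list was just past the threshold (camera adjusted p = 0.0485, adjusted p = 0.712 with an estimated correlation). Its median ran from 0.09 to 0.27 when each array was left out in turn. With the day as a random block 1 member was higher, and limma called 0 when 1 or the other zymosan array was left out, where 5 had an unadjusted p under 0.05. Camera's call was lost without zymosan replicate 1 (adjusted p = 0.104), zymosan replicate 2 (adjusted p = 0.0632) or unstimulated replicate 2 (adjusted p = 0.292), where 3 members were higher and the median was 0.09 against 0.15 with all arrays. Without unstimulated replicate 1, 2 members were lower.

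Macrophage identity genes were lower on balance. Of 21 measured, 9 fell and 2 rose, or 10 and 3 adjusted over the list alone. Cx3cr1 was 6.80-fold lower and the high-affinity IgG receptor Fcgr1 2.15-fold lower. Adgre1, a surface receptor typical of mouse macrophages, fell by 0.82 and Csf1r, the receptor of M-CSF, by 0.40. The transcription factor Tfec rose 2.73-fold and Gpnmb 2.04-fold. The list median was -0.39 (camera adjusted p = 0.00679, adjusted p = 0.554 with an estimated correlation), and -0.24 without unstimulated replicate 2 (camera adjusted p = 0.0453). Within the unstimulated pair its median was -0.08 (unstimulated 1 minus unstimulated 2), outside the central 95% of random lists (-0.06 to 0.12). With the day as a random block 5 members were lower, and 2 when 1 or the other zymosan array was left out.

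**Figure D3:**
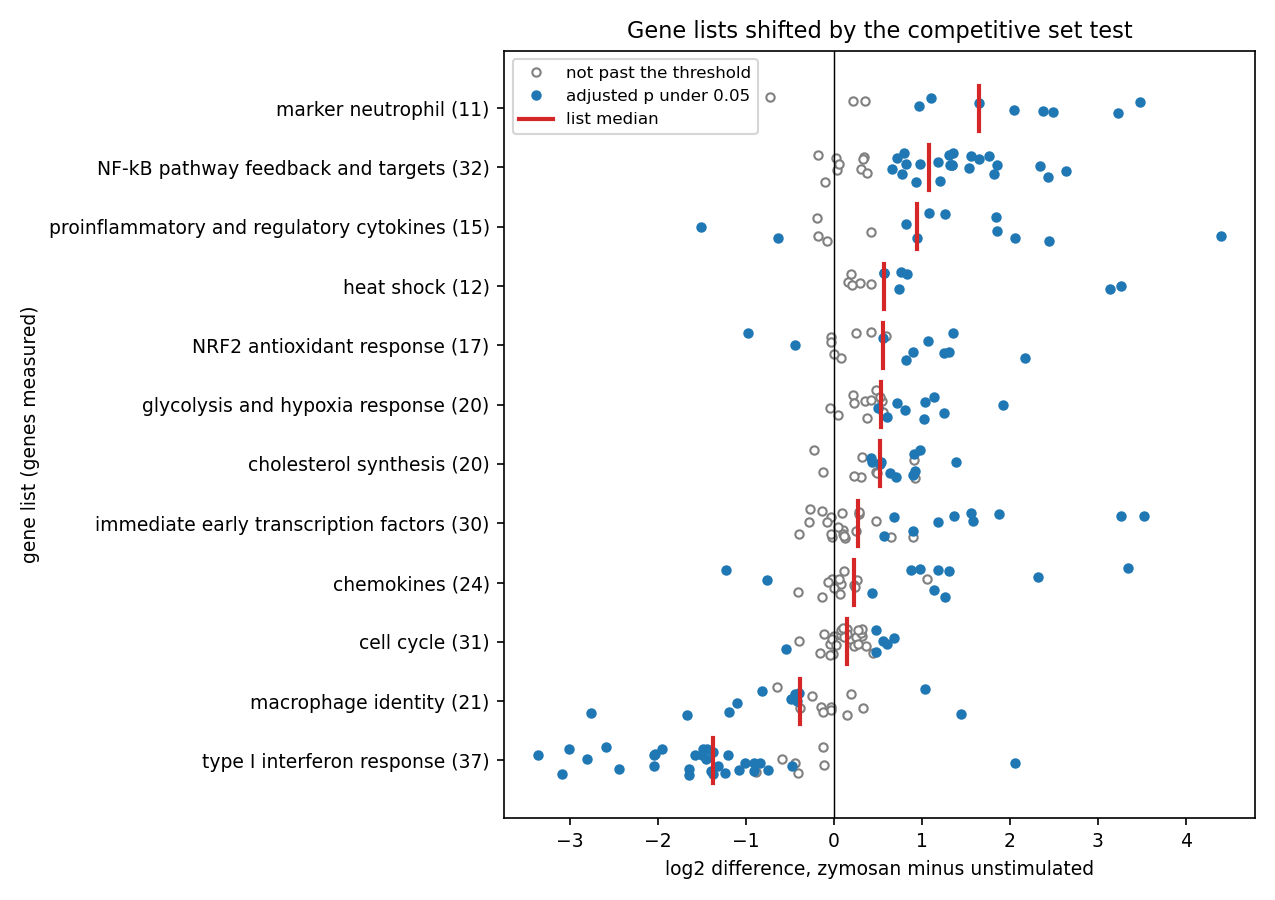
Log2 difference, zymosan minus unstimulated (x axis), of every measured gene in the 12 lists called by camera at the preset correlation (y axis, number of genes in brackets). Filled points passed the threshold, open points did not, and red bars are list medians, from -1.38 for the interferon list to 1.65 for neutrophil markers.

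Recognition receptors and adaptors moved in both directions. Of 40 measured, 10 rose and 8 fell, or 12 and 10 adjusted over the list alone, and the list was not called (camera adjusted p = 0.841). The C-type lectins Clec4n, or Dectin-2, and Clec4e, or Mincle, rose 3.79-fold and 2.78-fold, Irak2 rose 2.35-fold and Tlr2 2.41-fold. Clec7a, or Dectin-1, rose 1.39-fold (adjusted p = 0.043). Itgam, a subunit of complement receptor 3, was 3.17-fold lower and Tlr4 fell by 0.89. Syk, the kinase downstream of Dectin-1, rose 1.60-fold at the probe set that represented it (adjusted p = 0.0097) and fell by 1.62 at another (adjusted p = 0.00449). Card9 had no probe set with a single symbol here. Without zymosan replicate 1 or zymosan replicate 2, 4 members were higher and 2 lower each time, and with the day as a random block 8 and 5.

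Eicosanoid genes were also mixed, with 6 of 20 higher and 2 lower, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.453). The prostanoid receptor genes Ptger2 and Ptgir rose 4.02-fold and 3.81-fold, and Ptger3 rose at least 2.70-fold from below the filter's level, while Hpgds fell by 0.72 and Cysltr1 by 1.13. NFAT and calcineurin targets split evenly at the probe sets that represented them, with 4 of 11 higher and 4 lower, the same numbers adjusted over the list alone (camera adjusted p = 0.925). Fry called the list higher (fry adjusted p = 0.00927). Egr3 and Nr4a3, not called there, rose at another probe set, by at least 30.6-fold (adjusted p = 0.0011) and by 1.09 (adjusted p = 0.0269). The calcineurin regulator Rcan1 rose 4.91-fold and Nfam1 was 5.13-fold lower. Of 25 MAP kinase and receptor feedback genes, 6 rose and 5 fell, or 8 and 5 adjusted over the list alone (camera adjusted p = 0.661). Socs3 rose 3.88-fold and the phosphatase Dusp4 1.80-fold, whereas Dusp6 was 5.61-fold lower and Socs1 at least 1.47-fold lower. Without zymosan replicate 1 or zymosan replicate 2, 3 and 4 eicosanoid genes, and 1 MAP kinase feedback gene each time, were higher. Limma called 0 lower in either list then, where 4 and 3 eicosanoid genes and 5 MAP kinase feedback genes each time had an unadjusted p under 0.05. Of the NFAT targets, 2 and 3 were lower and 4 higher each time. With the day as a random block, 2 MAP kinase feedback genes were higher and 1 lower, and limma called 0 eicosanoid genes lower, where 3 had an unadjusted p under 0.05. Without unstimulated replicate 1, 4 eicosanoid genes were lower.

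Among the oxidase and nitric oxide genes, 1 of 8 rose, 1 also when adjusted over the list alone. It was Acod1, the itaconate-producing enzyme, at 7.61-fold. Nos2 differed by -0.12 (adjusted p = 0.491), Rac2 by -0.27 and Ncf4 by -0.21. The list median was -0.11 and its mean 0.29, and camera did not call it (adjusted p = 0.908). Without unstimulated replicate 2, 2 members were higher.

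The 7 other lists did not pass camera's test with all 4 arrays. LXR targets had 2 of 14 genes higher, Scd1 (4.35-fold) and Scd2 (2.58-fold), and 2 lower, Pltp (5.47-fold) and Lpl (1.63-fold), or 3 and 2 adjusted over the list alone (adjusted p = 0.686). Scd2 fell by 1.25 at another of its probe sets (adjusted p = 0.00612). ER stress genes had 4 of 18 higher, with Cebpb (1.81-fold) and Ppp1r15a (1.71-fold), and 1 lower, or 4 and 2 adjusted over the list alone (adjusted p = 0.154). Chemotactic and purinergic receptors had 2 of 18 higher, with Gpr35 (at least 2.22-fold), and 5 lower, with P2ry6 (2.20-fold) and C5ar1 (2.10-fold), or 3 and 6 adjusted over the list alone (adjusted p = 0.121). Antigen presentation genes had Cd86 (2.49-fold) and Cd274 (2.39-fold) higher and Cd74 (2.14-fold) lower among 15, and the counts adjusted over the list alone were also 2 and 1 (adjusted p = 0.385). Alternative activation genes had Chil3 (8.80-fold) and Tgm2 (2.59-fold) higher among 10, also 2 adjusted over the list alone (adjusted p = 0.453). Lysosome and autophagy genes had 4 of 21 higher, with Ctsk (3.47-fold) and Npc1 (1.52-fold), or 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.187). Apoptosis regulators had 3 of 15 higher, Fas (2.09-fold), Mdm2 (1.87-fold) and Bcl2l11 (1.51-fold), and Bbc3 (1.63-fold) lower, or 3 and 3 adjusted over the list alone (adjusted p = 0.927). Another probe set of Bcl2l11 fell by 0.93 (adjusted p = 0.01). For apoptosis regulators whose representing probe set did not pass, other probe sets past the threshold rose for Mcl1, by 0.61 to 0.67. They fell for Bcl2l1, by 1.39 and 1.48, and for Bak1, Bid and Xiap. Without unstimulated replicate 1, camera called the ER stress list higher (adjusted p = 0.0172, median 0.44) and the chemotactic and purinergic receptors lower (adjusted p = 0.0157, median -0.16). In that setting 9 ER stress genes were higher, and 5 LXR targets and 3 alternative activation genes lower. Without unstimulated replicate 2, 5 LXR targets were higher, and 8 chemotactic and purinergic receptors, 4 antigen presentation genes, 3 apoptosis regulators and 1 lysosome gene lower. Without zymosan replicate 1 or zymosan replicate 2, each of these 7 lists had at most 1 gene higher and 1 lower, and with the day as a random block at most 2 higher and 3 lower. The LXR, ER stress, chemotactic receptor and antigen presentation lists, as well as the MAP kinase feedback and recognition receptor lists, also had a median within the unstimulated pair outside the central 95% of random lists.

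Housekeeping genes had Tfrc (3.34-fold) higher and Ywhaz (1.57-fold) lower among 11, also 1 and 1 adjusted over the list alone (camera adjusted p = 0.914). Other probe sets of Tfrc differed by 0.15 and -0.66 and did not pass the test. Actb differed by -0.32 (SE 0.10, adjusted p = 0.0716) at the probe set that represented it and fell by 2.53 at another (adjusted p = 0.0135), and Gapdh had no probe set with a single symbol here. Limma called 0 housekeeping genes lower without zymosan replicate 1 or zymosan replicate 2, and with the day as a random block, where 1 had an unadjusted p under 0.05, and 0 without unstimulated replicate 2, where 3 had. Without unstimulated replicate 1, 2 housekeeping genes were higher. The median difference over all kept probe sets was -0.01.

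Among markers of other cell types, those of neutrophils rose. Of 11 measured, 8 rose, or 9 higher and 1 lower adjusted over the list alone. Mpo rose 9.40-fold, S100a8 5.62-fold, S100a9 5.21-fold and Ngp 3.15-fold. S100a8 reached 10.83 ± 0.03 against 8.34 ± 0.23 (SD, n = 2). Ltf (0.36), Chil1 (0.22) and Mmp9 (-0.73) did not pass the test. The list median was 1.65 (camera adjusted p = 1.52e-07, adjusted p = 0.326 with an estimated correlation), and without zymosan replicate 1 or zymosan replicate 2, 8 and 7 members were higher. Without unstimulated replicate 1, 1 member was lower. These markers rose together with cytokine, chemokine and NF-kB genes, on the same arrays on which macrophage identity genes were lower on balance.

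Markers of the remaining cell types were not called as lists by camera, while fry called B cell markers lower (adjusted p = 0.02) and erythroid and megakaryocyte markers higher (adjusted p = 0.0259). T and NK cell markers had Cd28 (5.23-fold) higher among 8, 1 also adjusted over the list alone (camera adjusted p = 0.966), with Cd3e at -0.19. B cell markers had Cd79b (1.49-fold) and Ighm (2.12-fold, at 1 of its 7 probe sets) lower among 8, also 2 adjusted over the list alone (adjusted p = 0.362). Dendritic cell markers had Itgax (1.90-fold) lower among 8, also 1 adjusted over the list alone (adjusted p = 0.686), and stromal markers had Postn (at least 1.24-fold) lower among 8, also 1 adjusted over the list alone (adjusted p = 0.154). Of 6 erythroid and megakaryocyte markers Tfrc was higher, at 1 of its 3 probe sets, also 1 adjusted over the list alone (adjusted p = 0.353). When 1 or the other zymosan array was left out, limma called 0 B cell, dendritic or stromal markers lower, where 2, 1 and 1 had an unadjusted p under 0.05. With the day as a random block it called 1 dendritic marker and 0 B cell or stromal markers lower, where 2 of each of the latter had an unadjusted p under 0.05. The 3 mast cell and basophil markers kept, Gata2 (0.18), Tpsb2 (0.11) and Hdc (-0.07), did not pass and were too few for the set test, though Gata2 passed without unstimulated replicate 1 (0.41, adjusted p = 0.0481). Xist, the single sex-linked gene kept, differed by 2.51 (SE 1.52, adjusted p = 0.314), since it was at 5.78 on unstimulated 1 and between 10.80 and 11.02 on the other 3 arrays, and it passed without unstimulated replicate 2.

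Measures of RNA quality moved with the groups too. The 3' minus 5' signal of the control probe sets was higher on the zymosan arrays for Actb (0.50 ± 0.03 against 0.17 ± 0.03, SD, n = 2), Gapdh (0.29 ± 0.09 against -0.13 ± 0.04) and Tfrc (2.26 ± 0.13 against 1.24 ± 0.04). A higher value means relatively less signal from the 5' end of the transcript. The arrays of the groups did not overlap in these 3 measures, and the smallest 2-sided exact p that 2 against 2 allows is 0.333. The 5' probe set of 18S ribosomal RNA was at 8.53 ± 1.04 in unstimulated and 6.32 ± 0.07 in zymosan arrays. Probe sets of 1 gene also disagreed. Of 669 genes with at least 2 probe sets past the threshold, 75 (11.2%) were called higher by one and lower by another, and among 520 kept list genes 42 had another probe set past the threshold where the chosen one was not, or in the opposite direction. Named genes past the threshold that had at least 1 other probe set not past it also included Egln3, P4ha1, Pfkl, Sc5d, Hsph1, Mdm2, Rrm1, Scd1, Tlr4 and Ywhaz. Clec7a and Csf1r passed when adjusted over genes and not when adjusted over probe sets.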

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

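The tests of the interferon and NF-kB genes, and of markers of other cell types, were chosen after those results were seen. The second granulocyte panel was also drawn up after the result of the granulocyte markers, in place of a test on 6 granule genes among them, of which 5 rose, but before the values of the panel itself were seen. The test of the other splits of the arrays was set before its values were seen. Control probe sets outside the main measurement differed between the groups. The 3' minus 5' signal was higher on the zymosan arrays by 0.33 for Actb, by 0.42 for Gapdh and by 1.02 for Tfrc (log2). The poly(A) spikes, RNAs added before labelling, were higher by 0.50. In the other direction, the 18S ribosomal 5' probe set differed by -2.21 and the hybridization spikes by -0.26.

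Of the 3 ways to split the 4 arrays into 2 and 2, 1 gave as many calls, the real one, with 4393 probe sets. The highest of the other splits gave 0 by limma, where 160 and 91 probe sets had an unadjusted p under 0.05. With 3 splits no share under 0.05 can be reached. Each of the other splits put 1 array of each group on each side, so any difference between the groups widened the spread within the sides. The real split also kept the same-day zymosan arrays together, so these counts do not tell zymosan from day.

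Interferon response genes were lower on the zymosan arrays. Sex of the animals, by which unstimulated 1 appears to differ in its sex-linked genes, is argued against as the whole cause, since unstimulated 2, with the sex-linked pattern of the zymosan arrays, still lay above them by a median of 1.14. What stays open is that cultures or processing days differ in interferon activity whatever the stimulus, since the list also differed by a median of 0.50 between the unstimulated arrays of different days, outside the central 95% of random lists (-0.04 to 0.12). These arrays also differ in their sex-linked genes and titles, so that difference cannot be assigned to day or culture. Other lists lay outside the range of their random lists too, with medians from -0.16 to 0.36. They were the immediate early, MAP kinase feedback, recognition receptor, NRF2, sterol, LXR, glycolysis, ER stress, macrophage identity, chemotactic receptor and antigen presentation lists. The random lists were matched on mean expression only and not on genes moving together, so lying outside that range does not single out the interferon list. Across the 37 genes, which are not independent, the difference within the unstimulated pair went with the decrease after zymosan (r = 0.64, permutation p = 1e-05, the smallest 100000 resamples can give, and rho = 0.60, permutation p = 0.00012, against r = -0.03 over all kept genes). Both unstimulated arrays enter both of these values, and permuting genes does not allow for that. The correlation therefore does not tell the causes apart. An effect of zymosan is also open and was not tested, because no day held both groups.

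Granulocyte markers were higher on the zymosan arrays. A lower share of macrophages that raises every other cell type alike was tested with 32 markers of T and NK, B, dendritic and stromal cells. The 11 granulocyte markers exceeded these by a mean of 1.61 (2-sided permutation p = 3e-05, over genes that are not independent). The test cannot exclude that explanation, since markers of absent cells cannot rise. Several of the 32 lay near the filter's level on the unstimulated arrays, such as Zbtb46 (4.68), Pdgfra (4.80) and Col1a2 (5.14). More granulocytic cells among the cultured cells is a candidate explanation that met its test on a second panel of 12 genes, where 5 of the 9 genes past the filter rose, Ctsg (1.60), Trem3 (0.79), Anxa3 (0.69), Ms4a3 (at least 0.58) and Pglyrp1 (at least 0.07). The test would not have been met with 4 of the 9, and Ms4a3 and Pglyrp1 rose from below the filter's level. Anxa3 was already at 11.10 on the unstimulated arrays, so its rise need not come from granulocytic cells. Macrophages can also express some of the granulocyte genes, among which S100a8 reached 10.83 and Mmp8 9.10. A response to zymosan or a difference between cultures stays open and untested.

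NF-kB feedback and target genes were higher on the zymosan arrays. Variation between days of the kind seen within the unstimulated pair is argued against, since the median absolute difference of the list there was 0.17 against a median change of 1.08. A difference particular to the day and operator of the zymosan arrays cannot be told apart from zymosan, since 0 processing days held arrays of both groups. That zymosan raised these genes without MyD88 is a hypothesis that these arrays leave open.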

How the results depend on the processing

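The random day block was chosen after seeing the data. The counts of calls moved most. With adjusted p under 0.01, 566 probe sets were higher and 500 lower. With a minimum fold of 1.5 under treat, 253 and 197 probe sets and 135 and 76 genes of at least 2-fold were called. With the processing day as a random block, 741 and 647 probe sets were called. Leaving out each array in turn gave 231 to 2531 probe sets higher, 157 to 2280 lower, 161 to 341 genes higher and 100 to 235 lower by 2-fold, the lowest without zymosan replicate 2, where the lone array was assumed to vary like the unstimulated pair. Of the 277 and 209 genes, 156 and 96 were called there, and 244 and 182 under the random block. With an estimated correlation camera called 0 lists higher and 0 lower, against 10 and 2, with 3 and 0 at an unadjusted p under 0.05, and fry called 13 and 2. The estimated correlation was negative for the NF-kB, neutrophil, heat shock, chemokine and cytokine lists (-0.05 to -0.02). Genes moving together therefore do not account for the loss of those calls. That form takes its degrees of freedom from the 4 arrays, so a call lost there does not by itself single out a list. Fry's calls held 8 of camera's 12 lists and left out the interferon (adjusted p = 0.0664), glycolysis (0.0769), NRF2 (0.105) and cell cycle (0.137) lists. Its other 7 were eicosanoid, NFAT, alternative activation, phagocyte oxidase, housekeeping and erythroid genes, higher, and B cell markers, lower. The mean SD of differences between groups was 0.51 over kept and 0.43 over all probe sets. With the mean of all probe sets of a gene, Syk was at -0.24, Gp1bb at -0.017 and Egr3 at 2.94, since it averages probe sets that differ. Signs that turned without 1 array were those of uncalled genes, with ranges over the 4 arrays left out in turn of -0.043 to 0.41 for Gata2, -0.0055 to 0.22 for Tpsb2, -0.17 to 0.020 for Hdc, -0.40 to 0.10 for Itga2b, -0.028 to 0.21 for Ticam1 and -0.11 to 5.13 for Xist, which unstimulated replicate 1 alone held low. Fry gave the opposite sign to camera for 3 lists that camera did not call, and the cause was not tested. It called phagocyte oxidase (median -0.11, fry adjusted p = 0.0226) and housekeeping genes (median 0.0091, fry adjusted p = 0.0116) higher, and did not call antigen presentation (fry adjusted p = 0.856). Of the 8 oxidase genes Acod1 alone passed limma's threshold, and of the 11 housekeeping genes Tfrc alone rose and Ywhaz alone fell. Those fry calls therefore need not describe the lists as a whole. Of the 141 named genes, 111 of them called, 21 calls were lost under the random block, 53 under treat, 29 at adjusted p under 0.01, and 49 and 50 without zymosan replicate 1 and 2. No paired analysis was possible because the labels give the groups no shared replicate numbers. The offset for linear values was not run, since the values are log2, and array weights changed no call among named genes and were equal within each group. Signal near the background limits genes below the filter, such as Il6 and Ifnb1, and those whose fold is given as a bound.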

Other observations

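Families of genes by symbol, 15 with at least 5 kept genes, were chosen after the lists had been seen and added energy and translation genes of the mitochondrion. Of 43 genes of respiratory complex I and its assembly, 8 rose and 1 fell, among them Ndufb1 (0.66, SE 0.12) and Ndufs4 (0.52, SE 0.11), and the family median was 0.19. Of 73 mitochondrial ribosomal protein genes, 7 rose and 1 fell, among them Mrpl43 (0.49, SE 0.11) and Mrpl38 (0.46, SE 0.10), with a median of 0.17. Over all 13220 kept genes, 1335 rose and 890 fell, so 7 of 73 is no excess of increases. Another probe set of Ndufs4 and another of Mrpl38 did not pass the test. Both families were called by camera (adjusted p = 0.0045), and neither with the correlation taken from the data (adjusted p = 0.523 with an estimated correlation). The 50 cytosolic ribosomal protein genes had a median of 0.02 (adjusted p = 0.745). The 13 families other than the first pair were not called (adjusted p from 0.153 to 0.916).

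Single genes in the other families moved more than their families. Of 51 Rab GTPases, 8 fell and 1, Rab20, rose by 1.55 (SE 0.11), while Rab5c, of early endosomes, was at -1.60 (SE 0.20) and the family was not called (adjusted p = 0.153). Tnfrsf11a, the receptor RANK, was at -1.40 (SE 0.10) and Tnfrsf1b, a receptor of TNF, at 0.79 (SE 0.10), both past the threshold, although another probe set of Tnfrsf1b fell by 0.90 (adjusted p = 0.0312). Slc30a1, a zinc exporter, rose by 1.45 (SE 0.10), while another of its probe sets differed by 0.38 (adjusted p = 0.119). Ddx58 and Ddx60, RNA sensors induced by interferon, were at -1.65 and -2.18.

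Sex-linked genes set unstimulated 1 apart. Eif2s3y, on the Y chromosome, was at 8.30 there and at 2.98, 3.02 and 3.19 on unstimulated 2 and the zymosan arrays, and Uty was at 5.62 against 2.94, 3.39 and 3.13. Xist went the other way, at 5.78 against 11.02, 11.02 and 10.80. The labels give no sex.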
